A study of Dictyostelium discoideum with 40 samples.

How the data were processed

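RNA was measured on 2-colour Agilent arrays in NC105.1-RFP cells, a wild strain of Dictyostelium discoideum that carries a red fluorescent protein. Per the labels, labelled and unlabelled amoebae were mixed in equal amounts, spread on 2 plates per mixture and harvested after 4, 8, 12, 16 or 20 h of development, and the red cells were recovered by fluorescence-activated sorting. The unlabelled partner was NC105.1 itself in the self mixes and the strain NC85.2 in the chimeric mixes. This gave 10 groups of 2 plates, and each of the 20 plate samples was hybridised in 2 dye orientations against a common reference of NC105.1-RFP RNA pooled from 0 to 20 h, which made 40 arrays. The labels call the plates biological replicates although both came from one mixture, so the p-values measure the spread between these plates.

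The scanner files hold the median intensity of each spot and of its local background for both dyes, per the file headers without normalization, as extracted by the authors with Agilent Feature Extraction 10.7.3.1. The deposited log ratio column is a log10 of red over green processed signals, which that software background-subtracted and dye-normalized. The authors' table of values holds log2 of sample over reference with the sign of Cy3-labelled samples already turned. Its scale and direction were found by setting each column against the same array's scanner values, with correlations of 0.983 to 0.999 over spots. Its normalization method and centring stay unknown, and its column medians ran from -0.12 to 0.26. The submitters' notes name limma without further steps.

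The ratios were computed from the spots' median signals, because the mean signals that had been planned were not used here. Background was corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), and each array was normalized by loess with control spots at weight 0. Spots marked as outliers were left out, and the sign of Cy3-labelled samples was turned. No spot was saturated. Spots of a probe and then the probes of a gene were averaged; the array carries 43803 gene spots and 32199 probes for 10858 genes, of which 10586 have 3 probes. Of these genes, 10766 were matched to the reference gene table by locus identifier and 92 kept the name in the files. Probes with most of their spots well above background in the sample's channel on at least 4 of 40 arrays were kept. Genes were averaged over their kept probes, which left 10117 genes and dropped 741. For a gene bright in 1 kind of mix alone, probes passed through the arrays of that mix. The 2 arrays of a plate were averaged into 1 value. The data.table package (version 1.17.8) read the files, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

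Signal rather than counts set the depth: the median sample signal of an array ran from 85 to 459.5 against a median local background of 22 to 49, and 69 to 87.8% of spots were well above background. The number of arrays limits the precision. The 2 arrays of a plate correlated at 0.757 to 0.881 and the 2 plates of a group at 0.944 to 0.984 across genes, which are not independent replicates. The arrays lay on 5 slides and were scanned on 2 dates. Each date holds one dye orientation of every plate, so it cancels in the plate means. No slide holds both partners at one time, so no within-slide difference exists for a single time, and slide was instead fitted as a block.

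One linear model per gene (lmFit and eBayes of limma, 10 residual and 3.16 prior degrees of freedom) held the 10 groups. Contrasts gave the chimeric minus self difference at each time and its mean over the 5 times, and moderated F tests gave any difference at the 5 times, the interaction of partner and time, and change over time within each kind of mix. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All limma p-values are two-sided. On simulated data in which 50 genes per size were shifted in the chimeric mixes at every time, shifts of 0.5, 1, 2 and 3 on the log2 scale were recovered for 90, 94, 100 and 100% of genes with 12 false calls. With the shift at 12 h alone, 34, 72, 100 and 96% were recovered with 11 false calls. The simulated noise was normal and independent between plates, at each gene's residual spread. It held no differences between mixtures or slides and no likeness of same-numbered plates, so false calls from these are not counted.

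Gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Those tested were the tgr allorecognition family, cell adhesion, cAMP signalling and aggregation, counting factor and chalones, prestalk and stalk, prespore and spore, DIF-1 pathway, growth and feeding, ribosomal proteins, translation factors, proteasome, heat shock and chaperones, oxidative stress, autophagy, DNA replication and cell cycle, polyketide synthases, ABC transporters, actins, cytoskeleton and motility, calcium-binding proteins, transcription factors, sensor kinases and receptors, cellulose and matrix, peptidases, and candidate social genes. Discoidins and the hssl family had 1 measured member each, and cytochrome P450 and retrotransposons had 0, under the minimum of 3. The 25 lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists or, for single times, over the 125 list and time pairs. An exact two-sided permutation test of each list's mean exchanged partner labels within times (7776 arrangements, smallest possible p 0.000257). A limma fit to the mean of each list's genes per plate was added after seeing the data.

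The genes named were, for the mean over times, the 10 largest rises and falls among called genes with one sign in both dye orientations, and the 5 largest each way with a symbol of their own. For each time they were the 3 largest and the 2 largest with a symbol each way, for F tests the 5 smallest p, for development the same by the 20 h minus 4 h difference, and for described lists up to 4 members with the smallest p. A set of 14 developmental genes was to be named whatever their values; carA-1, dscA-1 and dscA-2 are not on the array. A gene none of whose probes was well above background on any array of a group has only a bound. It was computed as the bright group's mean normalized signal over the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background, per channel after loess and Aquantile. Where a gene was well above background on some arrays of the dim group, the fold is such a bound too and the number of those arrays is given.

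Alternatives were Agilent's processed log ratios, the authors' value table, no background correction, median centring in place of loess, quantile normalization of average intensities, no or a stricter filter (20 of 40 arrays), the brightest probe of a gene, each dye orientation alone, all 40 arrays with a dye term and the plate as a random block, slide as a fixed or random block, plate number as a block, a trended and robust variance model, fits to the groups of one comparison only, and each plate left out in turn. In the last case the lone remaining plate is assumed to vary like the other groups. Leaving 8 h or 20 h out of the mean was added after seeing the data.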

Results

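Gene expression was measured in NC105.1-RFP cells of Dictyostelium discoideum, a social amoeba whose starving cells aggregate and build a fruiting body of spores and stalk. The cells had developed for 4, 8, 12, 16 or 20 h in equal mixture with unlabelled NC105.1 cells (self mix) or with cells of the strain NC85.2 (chimeric mix). The series contrasts cooperation with self and with non-self, and the comparisons below ask how transcripts in the sorted cells differed with the partner. The purity of the sort is not known here. Any NC85.2 RNA among the sorted cells would thus enter each difference named below. There were 2 plates for each partner and time, 20 in all, and every value is a log2 ratio of the sorted cells over a common NC105.1-RFP reference. Time separated the plates most: the first principal component held 67.6% of the variance, and 15 of the 20 plates lay nearest to their own group of the 10.

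Development in the self mixes changed 9164 of the 10117 genes tested (90.6%; limma F test). From 4 to 20 h, ecmA, which encodes an extracellular matrix protein of prestalk cells, rose by 8.33 on the log2 scale (SE 0.25, 2 plates per time, adjusted p = 7.85e-11). hssB, of a family of small developmental proteins, rose by 9.82 (SE 0.36), and cad3, related to the calcium-dependent adhesion gene cadA, fell by 6.86 (SE 0.19). cafA, which encodes a calcium-binding protein, fell by 5.47 (SE 0.44). In the chimeric mixes 9104 genes changed (90%), with ecmA at 8.34, hssB at 10.17, cad3 at -6.75 and cafA at -5.65. The counts were 8362 and 8242 with slide as a block, when ecmA stood at 8.35 in self mixes (adjusted p = 6.18e-07).

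Averaged over the 5 times, 6 genes known only by locus identifiers were far higher in cells from chimeric mixes than in cells from self mixes (10 plates each). DDB_G0272706 was at least 32.1-fold higher (fitted log2 difference 6.05, SE 0.24), DDB_G0288417 at least 25.4-fold (5.44, SE 0.14) and DDB_G0288419 at least 23.1-fold (5.27, SE 0.14). DDB_G0272716 was at least 6.79-fold higher (3.06, SE 0.16), DDB_G0283429 at least 5.29-fold and DDB_G0278667 at least 4.57-fold. The difference was positive at 8, 12, 16 and 20 h for all of them, while at 4 h DDB_G0272706 and DDB_G0288419 were not well above background in either mix. Their adjusted p ran from 4.18e-11 to 6.53e-08. In self mixes DDB_G0272706, DDB_G0283429 and DDB_G0278667 were not well above background on any of 20 arrays, while DDB_G0288419 was on 1, DDB_G0288417 on 8 and DDB_G0272716 on 10. Each slide held as many self as chimeric plates, so the layout kept these mean log2 differences the same with slide as a block. That fit gave adjusted p from 2.11e-08 to 3.85e-06.

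**Figure D1:**
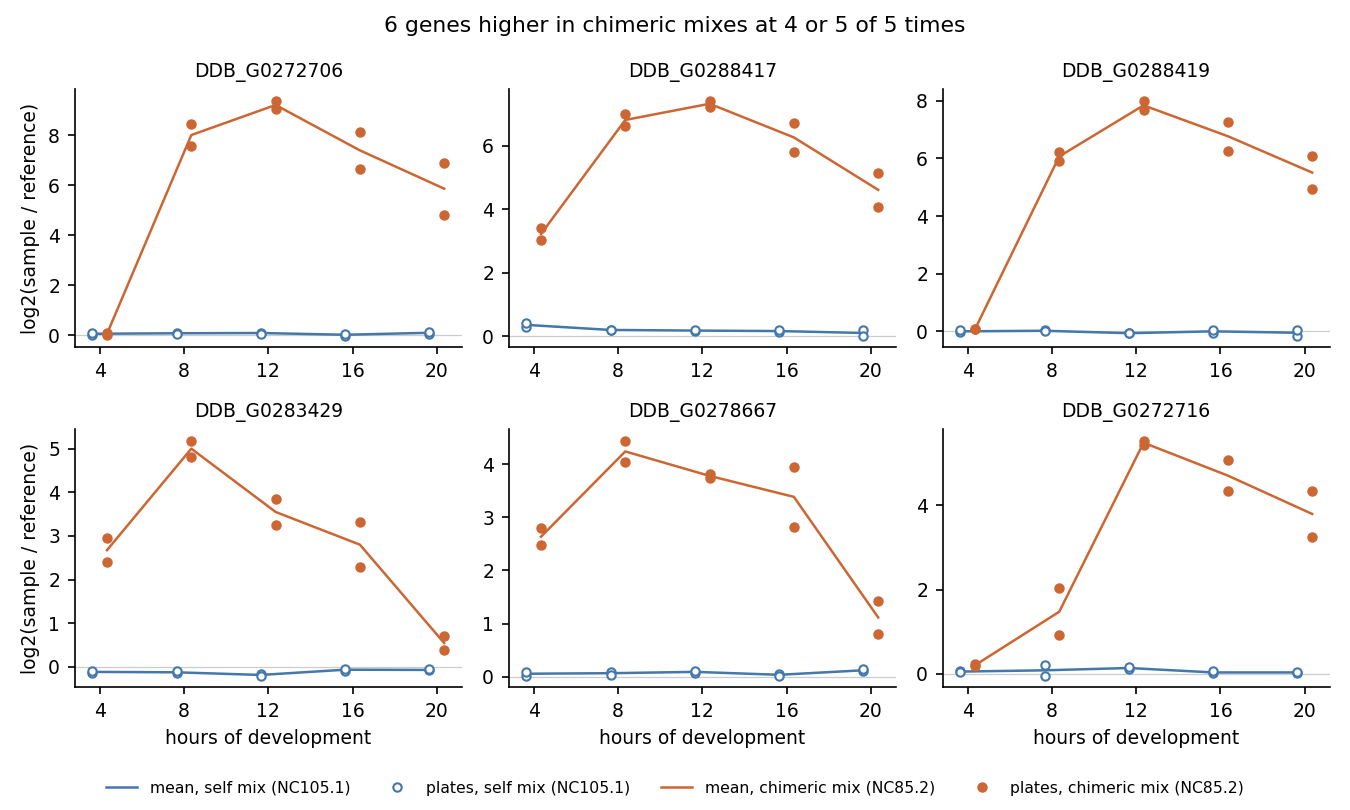
log2 of sample over reference (vertical axis, a separate scale per panel) against hours of development for the 6 genes, in self mixes (open points, 2 plates per time) and chimeric mixes (filled points), with lines through the means. In self mixes every gene stays near 0, and in chimeric mixes DDB_G0272706 rises from background at 4 h to a mean of 9.22 at 12 h.

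Among genes with symbols, the mean over times rose for comH (1.77-fold, log2 0.82, SE 0.14, adjusted p = 0.00437), for proA, which encodes profilin (1.66-fold), for phaZ (1.63-fold), for the polyketide synthase gene pks13 (log2 0.62, measured on 5 of 20 self and 6 of 20 chimeric arrays) and for cad2, a relative of cadA (1.48-fold). The rise of pks13 rests on 4 h, when its plates stood at 0.3 and 0.18 in self mixes and at 2.72 and 3.22 in chimeric mixes. At the later times all of its plates lay between -0.48 and -0.04. The mean over times fell most for DDB_G0284539 (at least 2.28-fold, measured on 18 of 20 chimeric arrays, -1.28, SE 0.10, adjusted p = 1.37e-05). Among symbols it fell for udkC (1.68-fold), for nog1, a GTPase gene of large ribosomal subunit assembly (1.62-fold), for gtaX, a GATA zinc finger gene (1.60-fold, 17 of 20 self arrays), for bysl, which encodes bystin of small subunit assembly (1.52-fold), and for tspC, a tetraspanin gene (1.51-fold). In all 832 genes were called, 331 higher and 501 lower in chimeric mixes, of which 10 and 1 changed at least 2-fold. When slide was fitted as a block 340 were called (139 and 201; 330 shared), comH, nog1 and bysl among them at adjusted p of 0.011, 0.011 and 0.00957, while gtaX (0.0501), tspC (0.116) and cad2 (0.0605) were not. The call of tspC was lost in 17 of the 20 fits that left out 1 plate (adjusted p up to 0.106, without chimeric plate 1 of 16 h) and that of gtaX in 13 of 20 (up to 0.0786, without chimeric plate 2 of 12 h). The count fell to 521 without chimeric plate 2 of 4 h, 492 without self plate 1 of 8 h, 482 without self plate 1 of 12 h and 428 without chimeric plate 2 of 12 h. It was 483 without self plate 1 of 16 h, 390 without chimeric plate 1 of 16 h and 512 without self plate 1 of 20 h. With 8 h left out of the mean it was 215.

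Of the gene lists, the 72 ribosomal protein genes shifted down on the mean over times (median -0.30, 46 lower and 0 higher; adjusted over the list alone, 72 lower). The camera test gave adjusted p = 3.45e-30, and adjusted p = 0.39 with an estimated correlation. DNA replication and cell cycle genes shifted up (median 0.14, 13 of 51 higher and 0 lower; adjusted over the list alone, 20 and 3), with adjusted p = 1.67e-07, and adjusted p = 0.39 with an estimated correlation. They include rnrA, the large subunit of ribonucleotide reductase (1.28-fold, adjusted p = 0.00469), and the replication factor gene rfc2 (1.29-fold, 0.00731). Cellulose and matrix genes shifted down (median -0.32, 5 of 22 lower and 1, eco1, higher; adjusted over the list alone, 10 and 1), with adjusted p = 0.000204, and adjusted p = 0.39 with an estimated correlation. Among them the cellulose synthase gene dcsA fell 1.21-fold and the expansin-like gene expl7 1.36-fold. eco1 entered the list through its symbol alone and is a cohesion rather than a matrix gene. Growth and feeding genes (6 of 27 lower; adjusted over the list alone, 8; adjusted p = 0.000428) and peptidases (4 of 16 lower; adjusted over the list alone, 6; 0.000658) share the cysteine proteinase genes cprF (1.37-fold lower) and cprG (1.37-fold lower). With an estimated correlation both stood at adjusted p = 0.39. Translation factors (3 of 8 lower; adjusted over the list alone, 5) had adjusted p = 0.000658, and adjusted p = 0.431 with an estimated correlation. Prestalk and stalk genes (2 of 24 lower; adjusted over the list alone, 2) had adjusted p = 0.02, and adjusted p = 0.393 with an estimated correlation. The exact permutation test called the cellulose and matrix, peptidase, growth and feeding, and prestalk and stalk lists (exact adjusted p = 0.0354 each). It did not call the ribosomal proteins (exact p = 0.0496, adjusted 0.138), the replication list (exact p = 0.0376, adjusted 0.138) or the translation factors (exact p = 0.0715, adjusted 0.162). In the fit to plate means with slide as a block, the ribosomal list differed by -0.29 (SE 0.08, adjusted p = 0.0276), the cellulose and matrix list by -0.30 (SE 0.06, 0.0105) and the replication list by 0.12 (SE 0.03, 0.0276).

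At 4 h the clearest difference was in pks13, which was 6.61-fold higher in chimeric mixes (log2 2.72, SE 0.12, 2 plates per group, adjusted p = 9.93e-08). DDB_G0288417 was at least 5.31-fold higher (measured on 3 of 4 self arrays), DDB_G0283429 was at least 4.23-fold higher, and gefO, of the Ras guanine nucleotide exchange factor family, was 1.88-fold higher (adjusted p = 0.00119). One gene was lower, DDB_G0268754 (1.44-fold, adjusted p = 0.0065). In all 33 genes were called, 32 higher and 1 lower. The prespore and spore list (23 genes, median -0.18, 0 called; adjusted over the list alone, 0) had adjusted p = 0.0299, and adjusted p = 0.931 with an estimated correlation; its median ran from -0.50 with slide as a block to 0 with median centring, and its slide-blocked plate means had adjusted p = 0.302. A block for slide left 10 genes called, all higher, with pks13 at 2.66 (adjusted p = 0.000214), gefO at 0.91 (0.141) and DDB_G0268754 at -0.53 (0.57). Median centring in place of loess also gave 10 and ended the calls of gefO and DDB_G0268754. The count was 17 without self plate 1, 195 without self plate 2 and 21 without chimeric plate 1. The call of DDB_G0268754 was lost without either chimeric plate (0.0563 and 0.0547).

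At 8 h 5 of 19 cell adhesion genes were higher in chimeric mixes (adjusted over the list alone, 5 higher and 1 lower). The list had adjusted p = 0.00926, and adjusted p = 0.957 with an estimated correlation. The calcium-dependent adhesion gene cadA was 3.12-fold higher (log2 1.64, SE 0.27, 2 plates per group, adjusted p = 0.00232), its relative cad2 4.60-fold (2.20, SE 0.29, 0.000586), and tgrB1, one of the polymorphic pair of self-recognition genes, 3.05-fold (1.61, SE 0.37, 0.0162). Its partner tgrC1 stood 1.48-fold higher without passing the test (0.57, SE 0.33, adjusted p = 0.377), and neither did the adhesion gene csaA (adjusted p = 0.999). The deviations of same-numbered plates correlated at 0.72 at 8 h, a pairing that these tests ignore. On plates 1 and 2 tgrC1 stood at 0.92 and 0.26 in self mixes and at 1.56 and 0.76 in chimeric mixes. comH was 4.29-fold higher (2.10, SE 0.31). The ribosome assembly genes bysl (4.18-fold, -2.06, SE 0.16, adjusted p = 4.34e-06) and nog1 (3.79-fold, -1.92, SE 0.21) and the gene DDB_G0293202 (3.98-fold) were lower. DDB_G0272706, DDB_G0288419 and DDB_G0288417 were at least 108-fold, at least 35.6-fold and at least 56.5-fold higher, the last measured on 1 of 4 self arrays. With slide as a block cadA (1.80, adjusted p = 0.0394), cad2 (2.25, 0.0305), comH (2.59, 0.00909), bysl (-1.98, 0.0066) and nog1 (-1.77, 0.0229) were called, and tgrB1 was not (1.96, 0.102). Its call was also lost without self plate 2 (0.15) or chimeric plate 1 (0.156).

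**Figure D2:**
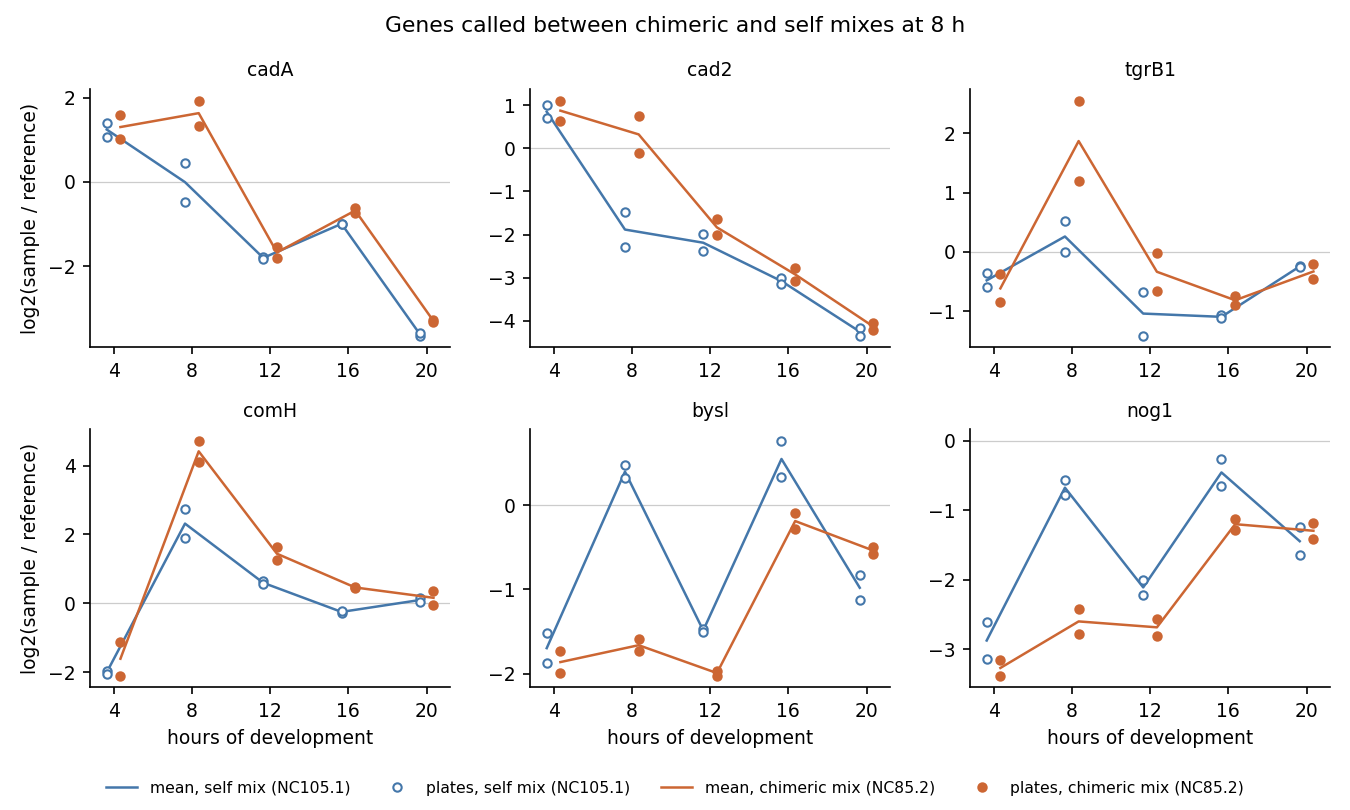
log2 of sample over reference (vertical axis, a separate scale per panel) against hours of development for 6 genes called at 8 h, in self mixes (open points, 2 plates per time) and chimeric mixes (filled points), with lines through the means. At 8 h cad2 averages 0.32 in chimeric and -1.89 in self mixes, and bysl -1.66 and 0.40.

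Of 51 DNA replication and cell cycle genes, 17 were higher and 2 lower at 8 h (adjusted over the list alone, 27 and 3; median 0.33), with adjusted p = 9.31e-08, and adjusted p = 0.429 with an estimated correlation. rnrA was 1.79-fold higher, the polymerase subunit gene polA2 1.81-fold and the kinase gene cdk7 1.75-fold, while the histone variant gene H3v1 was 1.78-fold lower (adjusted p = 4.65e-05). Of 26 tgr genes, 5 were higher (adjusted over the list alone, 8), among them tgrC5 (2.60-fold, adjusted p = 0.000994), tgrB2 (2.23-fold) and tgrL1 (1.82-fold). The list had adjusted p = 0.00141, and adjusted p = 0.931 with an estimated correlation. Of 83 cytoskeleton and motility genes, 7 were higher and 1 lower (adjusted over the list alone, 10 and 1), including the actin-bundling fimbrin gene fimA (2.38-fold) and limE (1.66-fold). That list had adjusted p = 0.00349, and adjusted p = 0.957 with an estimated correlation. Ribosomal proteins had a median of -0.13 (2 of 72 lower, rpl14 and rpl9; adjusted over the list alone, 2), with adjusted p = 0.0151, and adjusted p = 0.957 with an estimated correlation. Calls were lost for fimA without self plate 2 (adjusted p = 0.103), for tgrB2 likewise (0.0697), for limE without chimeric plate 1 (0.0554), and for rpl14 (0.185) and rpl9 (0.188) without self plate 1. In the fit to plate means, replication (adjusted p = 0.00893) and adhesion (0.0283) passed without a block, and with slide as a block none of these lists did: 0.125 for replication (median 0.35), 0.133 for adhesion (0.25), 0.075 for tgr genes (0.41), 0.423 for the cytoskeleton (0.21) and 0.886 for ribosomal proteins (-0.16).

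In all 837 genes were called at 8 h, 423 higher and 414 lower, of which 69 and 45 changed at least 2-fold. A block for slide left 155 called (81 and 74; 153 shared with those), and Agilent's processed ratios gave 486 higher and 826 lower, or 37.0% higher against 50.5%. The authors' table gave 489 and 822. Without self plate 1 the count was 399, without self plate 2 it was 309 and without chimeric plate 1 it was 440.

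At 12 h ribosomal protein genes were lower in chimeric mixes: 71 of 72 fell and 0 rose (adjusted over the list alone, 72 fell), with a median of -0.97. rps3a fell 2.00-fold (SE 0.14 on the log2 scale, 2 plates per group, adjusted p = 0.00343), rps4 2.12-fold and rpl11 2.39-fold. Translation factors fell with them (3 of 8; adjusted over the list alone, 5; median -0.57), such as the elongation factor 1 genes efaAI (1.54-fold) and efa1B (1.62-fold). Genes of secreted regulators of group size and proliferation fell in 3 of 10 cases (adjusted over the list alone, 7; median -0.53), namely countin, ctnA (2.10-fold, adjusted p = 0.00775), aprA (2.09-fold) and ctnC (1.68-fold). Growth and feeding genes (5 of 27 lower; adjusted over the list alone, 6) included cprF (2.47-fold). Peptidases (4 of 16 lower; adjusted over the list alone, 5) included cprG (2.13-fold), and among 14 oxidative stress genes the superoxide dismutase genes sodC (1.93-fold) and sodB (1.65-fold) were lower (adjusted over the list alone, 2). DNA replication genes stood higher (median 0.25, 1 of 51 called; adjusted over the list alone, 13 and 3), with orcD 1.41-fold higher. Without self plate 1 all of the single genes named here lost their calls, with adjusted p of 0.0626 for rps3a, 0.0691 for rps4, 0.116 for rpl11, 0.243 for efaAI, 0.166 for efa1B, 0.0861 for ctnA, 0.123 for aprA, 0.19 for ctnC, 0.0728 for cprF, 0.12 for cprG, 0.0761 for sodC, 0.272 for sodB and 0.317 for orcD.

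The camera test at 12 h gave adjusted p = 3.51e-89 for ribosomal proteins (0.362 with an estimated correlation), 2.56e-06 for translation factors (0.483), 0.000259 for counting factor and chalones (0.362), 5.94e-05 for growth and feeding (0.483), 0.000259 for peptidases (0.429), 0.00261 for oxidative stress (0.429) and 1.5e-07 for DNA replication (0.429); each value in brackets is an adjusted p. In the fit to plate means, added after seeing the data, ribosomal proteins differed by -0.96 (SE 0.15, adjusted p = 0.00152), and with slide as a block by -1.11 (SE 0.23, adjusted p = 0.0431). Counting factor and chalones (adjusted p = 0.0065), translation factors (0.0277) and growth and feeding (0.0333) also passed without a block. With slide as a block none of the other lists did: the adjusted p was 0.133 for translation factors (median -0.69), 0.125 for counting factor and chalones (-0.51), 0.277 for growth and feeding (-0.22), 0.458 for peptidases (-0.26), 0.35 for oxidative stress (-0.25) and 0.267 for DNA replication (0.31). With median centring in place of loess the medians shrank to -0.24 for translation factors, -0.08 for growth and feeding, -0.16 for peptidases and -0.07 for oxidative stress.

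**Figure D3:**
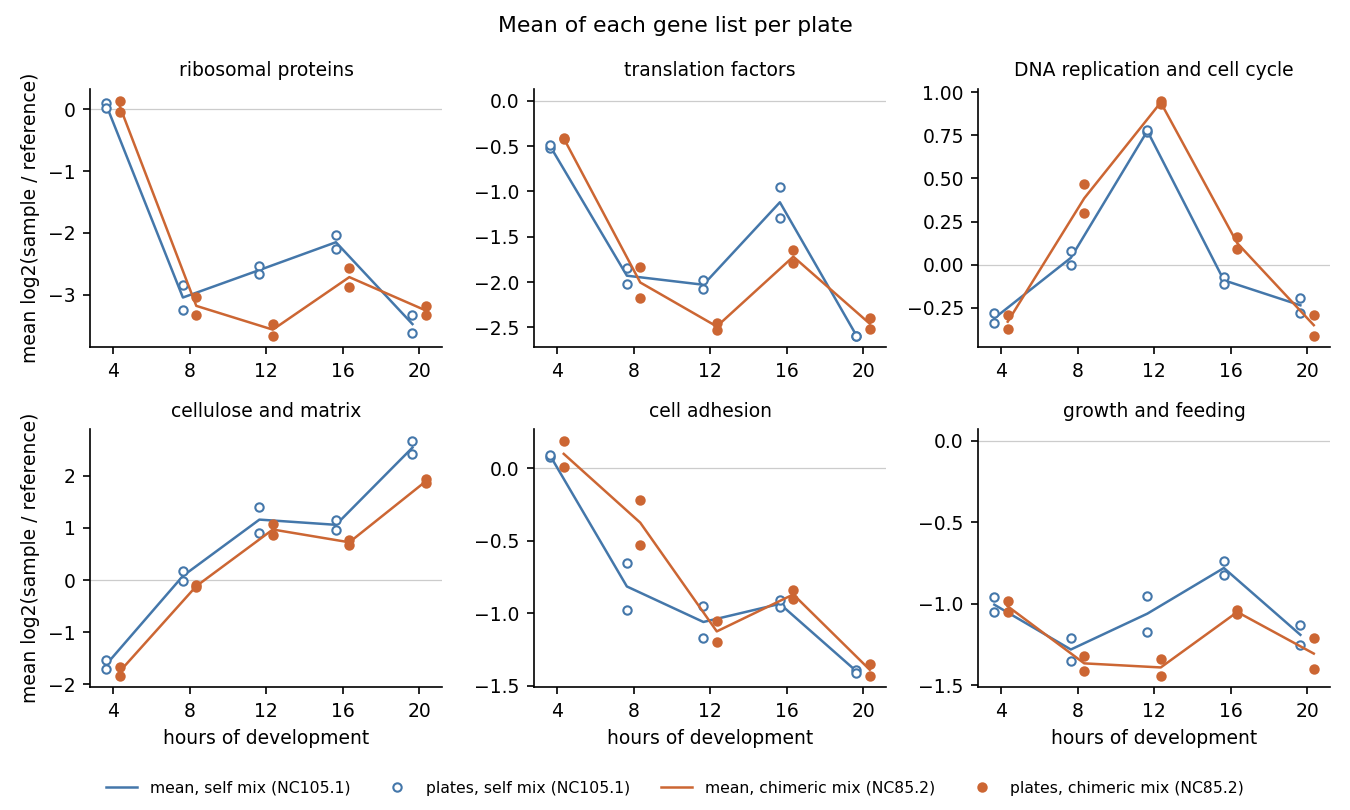
Mean log2 of sample over reference over the genes of 6 lists (vertical axis, a separate scale per panel) against hours of development, per plate in self mixes (open points) and chimeric mixes (filled points), with lines through the means. At 12 h both chimeric plates lie below both self plates for ribosomal proteins, a difference of -0.96.

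DDB_G0272706, DDB_G0288419 and DDB_G0288417 were at least 218-fold, at least 136-fold and at least 69.1-fold higher at 12 h (the last measured on 2 of 4 self arrays), phaZ was 1.90-fold higher and pks3 2.25-fold higher. DDB_G0269322 was 4.07-fold lower and DDB_G0274237 2.70-fold lower. In all 225 genes were called, 54 higher and 171 lower. A block for slide left 12 genes called, all higher, among them those 3 genes and pks3 (1.51, adjusted p = 0.035), while phaZ had 0.83 (0.148). rps3a then stood at -1.04 (0.147), rpl11 at -1.42 (0.148), ctnA at -1.09 (0.148), cprF at -1.45 (0.131) and DDB_G0269322 at -2.10 (0.131). Without self plate 1 the count was 14, without self plate 2 it was 116, without chimeric plate 1 it was 110 and without chimeric plate 2 it was 17. Without self plate 1 rps3a had adjusted p = 0.0626, phaZ 0.0826, pks3 0.122, DDB_G0269322 0.0543 and DDB_G0274237 0.0714. Of 31 named calls 3 held whichever of the 4 plates was left out.

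At 16 h ribosomal proteins were again lower (median -0.56, 8 of 72 called; adjusted over the list alone, 70), for example rps3 (1.81-fold, -0.86, SE 0.16, 2 plates per group, adjusted p = 0.0249). Of 8 translation factor genes 5 fell (adjusted over the list alone, 7; median -0.62), among them efaAI (1.76-fold) and efaAII (1.79-fold). Growth and feeding genes fell in 3 of 27 cases (adjusted over the list alone, 3), cprG by 1.06 on the log2 scale (SE 0.18). Among replication genes rnrA (1.52-fold) and H3v1 (1.33-fold) were higher, 2 of 51 (adjusted over the list alone, 10 and 1). Cellulose and matrix genes had a median of -0.40, and the 1 gene called was eco1 (1.52-fold higher; adjusted over the list alone, 1 and 0), which is on the list through its symbol alone and is not a matrix gene. The camera test gave adjusted p = 1.79e-38 for ribosomal proteins (0.483 with an estimated correlation), 5.29e-09 for translation factors (0.429), 0.00119 for growth and feeding (0.679), 2.07e-07 for replication (0.429) and 0.0365 for cellulose and matrix (0.931). Without chimeric plate 1 every single gene named here lost its call, with adjusted p of 0.277 for rps3, 0.242 for efaAI, 0.277 for efaAII, 0.277 for cprG, 0.408 for rnrA, 0.277 for H3v1 and 0.194 for eco1. In the fit to plate means ribosomal proteins (adjusted p = 0.0283) and translation factors (0.0065) passed without a block, and with slide as a block no list did, with adjusted p of 0.164 for ribosomal proteins (median -0.64), 0.125 for translation factors (-0.69), 0.545 for growth and feeding (-0.15), 0.158 for replication (0.28) and 0.486 for cellulose and matrix (-0.29).

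The vault protein gene mvpB (2.16-fold), eriA (2.14-fold), DDB_G0285549 (3.39-fold, -1.76, SE 0.22), DDB_G0280433 (2.93-fold) and DDB_G0281015 (2.82-fold) were lower at 16 h. DDB_G0272706, DDB_G0288419 and DDB_G0288417 were at least 61.4-fold, at least 57.1-fold and at least 34.7-fold higher (the last measured on 2 of 4 self arrays). In all 207 genes were called, 30 higher and 177 lower, or 14.5% higher against 25.3% with Agilent's processed ratios. A block for slide left 6 called, all higher, with DDB_G0285549 at -2.07 (adjusted p = 0.0795), rps3 at -0.88 (0.402) and mvpB at -0.92 (0.539). The count was 8 without self plate 1, 367 without self plate 2, 6 without chimeric plate 1 and 20 without chimeric plate 2 of that time. It was 133 without either chimeric plate of 4 h, 111 without either chimeric plate of 12 h and 313 without either chimeric plate of 20 h. Without chimeric plate 1 the adjusted p was 0.0912 for DDB_G0285549, 0.277 for mvpB, 0.317 for eriA, 0.277 for DDB_G0280433 and 0.277 for DDB_G0281015.

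At 20 h most called genes were lower in chimeric mixes in the main processing, though not with Agilent's processed ratios or the authors' table (counts below). DDB_G0284539 was 23.7-fold lower (-4.57, SE 0.23, 2 plates per group, adjusted p = 3.92e-07), DDB_G0276815 14.3-fold, DDB_G0285913 7.92-fold, the tetraspanin gene tspC 6.59-fold (-2.72, SE 0.37, 0.00144) and the GATA factor gene gtaX 6.43-fold (-2.69, SE 0.40, 0.00241). The first rose in self mixes to 4.35 at 20 h and stood at -0.21 in chimeric mixes. Higher were DDB_G0272706 (at least 28.4-fold), DDB_G0288419 (at least 26.4-fold, measured on 1 of 4 self arrays), DDB_G0288417 (at least 14.8-fold), ccdc25 (1.48-fold) and the translocon gene sec61a (1.44-fold). With slide as a block DDB_G0284539 stood at -4.65 (adjusted p = 9.9e-05), DDB_G0276815 at -4.45 (0.00269), tspC at -3.10 (0.0394) and gtaX at -3.40 (0.0117), while DDB_G0285913 (-3.67, 0.167), ccdc25 (0.61, 0.189) and sec61a (0.47, 0.31) were not called. The calls of ccdc25 and sec61a were also lost without self plate 1 (0.0903 and 0.234), and that of DDB_G0285913 without self plate 1 (0.176).

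**Figure D4:**
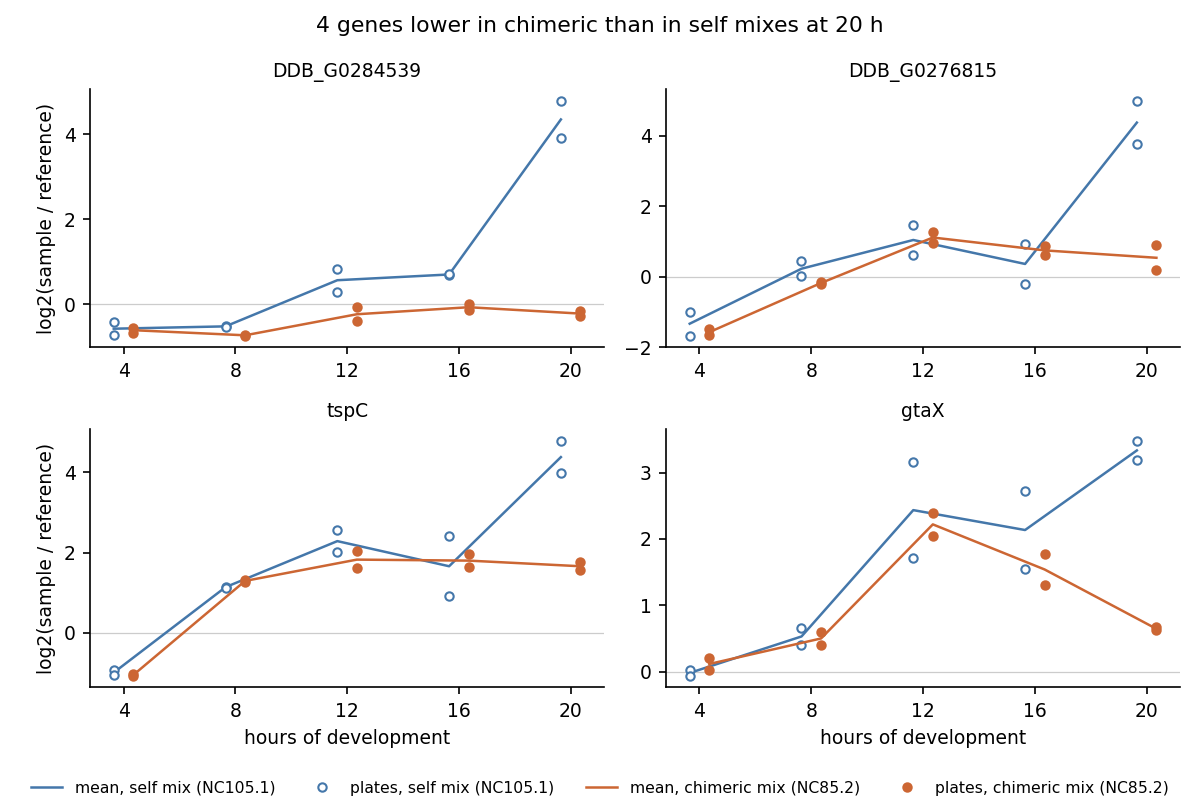
log2 of sample over reference (vertical axis, a separate scale per panel) against hours of development for 4 genes lower in chimeric mixes at 20 h, in self mixes (open points, 2 plates per time) and chimeric mixes (filled points), with lines through the means. At 20 h tspC averages 4.38 in self and 1.66 in chimeric mixes.

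Among lists at 20 h, cellulose and matrix genes had a median of -0.42 (1 of 22 lower, ecmI by 2.42-fold with adjusted p = 0.00208; adjusted over the list alone, 4), with adjusted p = 2.33e-06, and adjusted p = 0.362 with an estimated correlation. Their plate means differed by -0.65 (SE 0.14, adjusted p = 0.00893), and by -0.82 (SE 0.17, adjusted p = 0.0431) with slide as a block. Of 16 polyketide synthase genes, pks16 (1.81-fold) and pks17 (1.77-fold) were lower (adjusted over the list alone, 2), with adjusted p = 0.0302, and adjusted p = 0.931 with an estimated correlation. Of 9 DIF-1 pathway genes, dstC, a STAT gene, was lower (1.44-fold; adjusted over the list alone, 2), with adjusted p = 0.0302, and adjusted p = 0.483 with an estimated correlation. Ribosomal proteins stood higher (median 0.22, 0 of 72 called; adjusted over the list alone, 0), with adjusted p = 2.33e-06, and adjusted p = 0.957 with an estimated correlation. Their median turned to -0.02 with median centring in place of loess. With slide as a block the plate means of the other 3 lists did not pass, with adjusted p of 0.164 for polyketide synthases (median -0.31), 0.133 for the DIF-1 pathway (-0.36) and 0.6 for ribosomal proteins (0.31). Without self plate 1 the calls of pks16 (adjusted p = 0.0685), pks17 (0.105) and dstC (0.0841) were lost. In the slide-blocked fit ecmI had adjusted p = 0.0474, pks16 0.132, pks17 0.157 and dstC 0.123.

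In all 308 genes were called at 20 h, 35 higher and 273 lower, of which 127 fell at least 2-fold. Agilent's processed ratios gave 370 higher and 301 lower, or 55.1% higher against 11.4%, and the authors' table gave 371 and 300 genes. Median centring in place of loess gave 7 and 185, and no background correction 80 and 303. A block for slide left 94 called (4 and 90; 87 shared). The count was 184 without self plate 1, 134 without self plate 2, 152 without chimeric plate 1, and 470 without either self plate of 12 h.

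**Figure D5:**
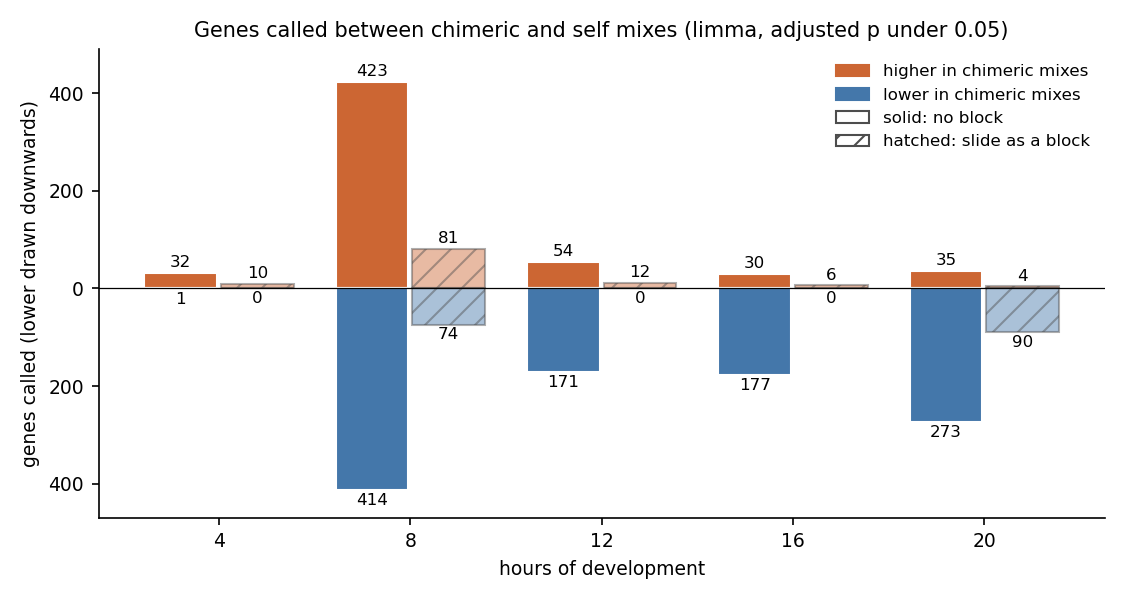
Number of genes called between chimeric and self mixes (limma, adjusted p under 0.05) at each time, higher drawn upwards and lower drawn downwards, without a block (solid) and with slide as a block (hatched). The number called peaks at 8 h with 423 higher and 414 lower, and with slide as a block the 8 h counts are 81 and 74.

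Over the 5 times 980 genes differed at 1 or more by the F test (128 with slide as a block), and for 380 the difference itself changed with time (26 with slide as a block). The smallest interaction p belonged to pks13 and DDB_G0288419 (adjusted p = 1.02e-05 each), DDB_G0284539 (5.45e-05), DDB_G0281035 and the cathepsin gene ctsZ (0.000229 each), with slide-blocked values of 0.00261, 0.00261, 0.00261, 0.0312 and 0.0409. The any-time F test was smallest for DDB_G0288417 and DDB_G0288419 (9.35e-10 each), DDB_G0272706 (7.59e-08), DDB_G0283429 (1.34e-07) and DDB_G0278667 (2.37e-07), with slide-blocked values of 6.62e-07, 6.62e-07, 1.83e-05, 9.39e-05 and 2.2e-05. Without a single plate the any-time count fell to 593 (self plate 1 of 8 h), 623 (self plate 2 of 8 h), 638 (chimeric plate 1 of 12 h), 553 (chimeric plate 2 of 12 h), 637 (self plate 1 of 16 h) or 548 (chimeric plate 1 of 16 h). The interaction count fell to 239 and 227 without plate 1 of either mix of 4 h, and 202 without self plate 2 and 247 without chimeric plate 1 of 8 h. It was 215 and 196 without chimeric plates 1 and 2 of 12 h, 194 and 240 without those of 16 h, and 153 without self plate 2 of 20 h.

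Partner differences were compared between times. Across genes, which are not independent replicates, the Pearson correlation was 0.65 (Spearman 0.46) between 12 and 16 h, 0.47 (0.32) between 8 and 16 h and 0.42 (0.20) between 8 and 12 h, and from -0.06 to 0.21 for the other 7 of 10 pairs. Of the 36 arrangements of partner labels within both times, counted in full after seeing the data, 4, 4 and 8 gave a size as large for those 3 pairs, and 4 is the fewest possible, so this design cannot set the resemblance apart from chance. Of the genes lower at 12 and at 16 h, 35 were shared against 2.99 for independent lists (Fisher's exact p = 4.57e-28, adjusted 4.57e-27), and of those higher at 8 and at 12 h, 34 against 2.26 (exact p = 5.38e-34, adjusted 1.08e-32), but of those lower at 8 and at 12 h 8 were shared against 7 (exact p = 0.401). Genes that vary together are not independent, so these p-values overstate the evidence. The genes lower at 20 h shared 3 with those lower at 12 h against 4.61 (exact p = 0.845) and 4 with those lower at 16 h against 4.78 (exact p = 0.708). Of the genes higher at 20 h, 6 were shared with 8 h against 1.46 (exact p = 0.00298), 4 with 12 h against 0.187 (exact p = 3.36e-05) and 4 with 16 h against 0.104 (exact p = 3.09e-06).

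Of the developmental genes named whatever their values, cadA was 1.40-fold higher on the mean over times (0.49, SE 0.12, adjusted p = 0.0256; 0.0604 with slide as a block). The others did not pass the test: tgrB1 (0.47, adjusted p = 0.102), tgrC1 (0.07, 0.837), the adhesion gene csaA (-0.01, 0.946), the adenylyl cyclase gene acaA (0.01, 0.965), the prestalk genes ecmA (-0.32, 0.103) and ecmB (-0.33, 0.106), the spore coat genes cotB (-0.05, 0.841) and cotC (0.09, 0.788), the prespore gene pspA (0.08, 0.679) and the cheater gene fbxA (-0.03, 0.927). Their standard errors ran from 0.08 to 0.16. The call of cadA was lost without self plate 1 of 4 h (0.0554), chimeric plate 2 of 4 h (0.0558), chimeric plate 1 of 12 h (0.0516), self plate 1 of 16 h (0.0514), chimeric plate 1 of 16 h (0.0526) or self plate 1 of 20 h (0.0541).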

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

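The tests below were chosen only after the results were seen, except for 4: the exchanges of partner labels for genes and for lists, the comparison with intensity-matched genes, and the measure of developmental pace after 16 h. The patterns to which the matched genes and the pace measure were applied are named by direction and time. Those patterns were thus themselves taken from the results.

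The effect of the partner differed between times for 380 genes (3.8% of those tested) by the interaction test. It also did so for 34 of the 58 genes that the naming rule picked for these comparisons other than as list members. Many of these were picked for large changes at single times or a small interaction p, so a high share was built in. The adjusted p was 1.02e-05 for pks13 and DDB_G0288419, 5.45e-05 for DDB_G0284539, 0.000229 for DDB_G0272706, DDB_G0281035, DDB_G0283301 and ctsZ, 0.000313 for DDB_G0272716, 0.000456 for DDB_G0283429 and bysl, and 0.000497 for DDB_G0288417. It was 0.0039 for DDB_G0293678, 0.00439 for DDB_G0278667, 0.00472 for eco1, 0.00551 for DDB_G0293202, 0.00749 for phaZ, 0.00856 for DDB_G0271188 and 0.00894 for DDB_G0276815. For gefO it was 0.0117, for cprF 0.0118, for nog1 0.0133, for DDB_G0290031 0.0144, for DDB_G0281433 0.0157, for DDB_G0268754 0.02, for DDB_G0274237 0.0202, and for DDB_G0284671 and DDB_G0269322 0.0205. The remaining genes were DDB_G0285549 (0.0237), tspC (0.0243), udkC (0.0286), cad2 (0.0303), DDB_G0269092 (0.0384), rpl11 (0.043) and gtaX (0.0435). Of 25 lists, the plate means of ribosomal proteins (0.0108), translation factors (0.0136) and DNA replication and cell cycle genes (0.0286) had a partner effect that differed between times. pks13 rose at 4 h, bysl fell at 8 h and DDB_G0284539 fell at 20 h, and with slide as a block 26 genes passed the interaction test.

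Exchanging the partner labels within times gave as many genes called on the mean over times as the real 832 in 1 of 100 splits, the real one included. A random exchange of plates thus rarely reached that count. It cannot exclude chance differences between mixtures, since both plates of a group came from 1 mixture. The highest other split called 821 and kept the real labels at 3 of 5 times, and the next, with 807, exchanged them whole at 3 of 5 times. The median other split called 1. The next below those called 483, 382 and 77, and grouping all plates by number gave 23 genes. For the lists, 30 of 100 splits called as many as the real 7 with camera (highest other 11, median 5), so chance was not excluded for the number of lists.

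The genes that rose by far the most, 7 at least 8-fold higher in chimeric mixes at 1 or more times against 2 at least 8-fold lower, were silent or faint in self mixes. An effect of one slide was argued against, since 100% of the 7 were called and higher with slide as a block. All 7 were also higher in each dye orientation, a weak test because they were chosen on the mean of both. The 2 arrays of a plate carry the same slide and position, so dye orientation cannot speak to slide. RNA of NC85.2 cells among the sorted cells was consistent with the values: 13 genes were seen on none of the 20 self arrays and on all 4 chimeric arrays of a time, against 2 of the reverse kind, a ratio of 6.5 (a gene was seen where at least 0.5 of its probes were well above background). Expression switched on in NC105.1 cells by the partner cannot be told apart from it, because just 1 of the 7 genes was well above background in the NC105.1-RFP reference on at least 20 of 40 arrays and the sequences of either strain were not analysed here.

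For the ribosomal protein genes lower at 12 h (median -0.97), intensity-dependent normalization was argued against by genes matched in intensity, whose median was -0.07 (10000 random lists of them, -0.14 to 0). A difference between slides was argued against by the list's mean, which was -0.96 (SE 0.15) without and -1.11 (SE 0.23) with slide as a block. The single genes lost their calls there because the errors grew, from a median of 0.142 to 0.189, and the residual degrees of freedom fell from 10 to 6, while the estimates of those named did not shrink. A shift in developmental time was measured in all other genes along the straight line from self 8 h to self 16 h. It would give 13.7% of the change (11.2 to 16.6 over 4 pairs of plates). The ribosomal list mean did not move in a single direction: in self mixes it was -3.04 at 8 h, -2.15 at 16 h and -3.47 at 20 h. In chimeric mixes it was -3.56 at 12 h. That line cannot speak to a shift towards a later or an unsampled stage. A response of translation genes to the partner is a candidate explanation that stays open. So do such a shift in stage, NC85.2 RNA among the sorted cells, which was not tested here, and a difference between mixtures. Each group came from 1 mixture.

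In the main processing 273 of the genes called at 20 h were lower in chimeric mixes. With Agilent's processed ratios or the authors' table more genes were called higher than lower, so the excess of lower genes depends on the processing. The 273 genes had medians of 1.44 and 1.54 on the self plates and 0.33 and 0.41 on the chimeric plates. At 16 h the medians were 0.25 and 0.36 in self mixes and 0.24 and 0.19 in chimeric mixes. RNA of NC85.2 cells lacking these transcripts, at the mixing share, would lower them by at most 1 on the log2 scale. Of the genes, 14.7% (40 of 273) were lower by more than that beyond their 95% interval. The genes were chosen as lower and the intervals are not adjusted for that choice, so this share can be too high. Slower development of chimeric mixes stays open. Over 2024 genes changed at least 2-fold in self plate 1 from 16 to 20 h, the chimeric change was 73.8% of that in self plate 2. Pairs of plates ran from 65.8 to 82.4% around the bound of 75% set for this test. Both self plates of a time came from the same mixture, so what set it apart enters the yardstick but not the chimeric mixes. A reduced share can thus arise at equal pace, and this test cannot decide. Of the 273 genes 161 were among those 2024, so the 73.8% is not independent of the genes to be explained. Over the 826 genes that fell in self plate 1, with 1 of the 273 among them, the share was 73.1%. The 273 genes themselves reached 17.3% of their change in self plate 2, well below that pace, but they were chosen as lower, so whether pace alone accounts for them stays open.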

How the results depend on the processing

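Leaving 8 h or 20 h out of the mean and the fit to list means were chosen only after the results were seen. All other alternatives were set beforehand.

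The counts of genes that changed over development stayed within 1.5 times their values under every alternative, plates left out included. With Agilent's processed ratios the mean over times gave 1396 genes, 4 h 19, 8 h 1312, 12 h 379, 20 h 671, any time 1605 and the interaction 842, and the median correlation of partner effects over pairs of times was 0.23 against 0.13. The authors' table gave 1407, 17, 1311, 377, 671, 1590 and 838 for the same counts. Without background correction the mean over times gave 1404, 8 h 1286, 12 h 362, 16 h 567, any time 1585 and the interaction 875. Median centring in place of loess gave 292 for the mean, then 10, 496, 72, 126 and 192 from 4 to 20 h, 529 at any time, 193 for the interaction and a correlation of 0.06. Quantile normalization of average intensities changes no ratio and tested nothing. The stricter filter on 20 of 40 arrays gave 14 genes at 4 h, with fewer genes tested. The cause of the other differences was not tested.

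Cy5-labelled samples alone gave 393 genes at 12 h, 418 at 16 h, 700 for the interaction and a correlation of 0.15. Cy3-labelled samples alone gave 175 for the mean, 15, 289, 78, 17 and 128 from 4 to 20 h, 223 at any time, 71 for the interaction and a correlation of 0.10; their signals were lower, with array medians from 85 to 181 against 189 to 459.5 for Cy5. All 40 arrays with a dye term gave 1378, 12 h 359, 16 h 534, 20 h 1004, any time 2116 and the interaction 1422.

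With slide as a fixed block the mean gave 340, the times 10, 155, 12, 6 and 94, any time 128, the interaction 26 and the correlation 0.06. This fit leaves 6 residual degrees of freedom instead of 10, and the median standard error at a single time rose from 0.142 to 0.189. The deviations of same-numbered plates from their groups correlated at 0.72 and 0.81 at 8 and 12 h but at -0.08, 0.13 and 0.05 at 4, 16 and 20 h, so the numbers did not pair the samples at every time. A replicate block gave 320 genes at 16 h. A replicate block within each time gave 1465 for the mean, 394 at 12 h, 431 at 16 h, 822 at 20 h, 1722 at any time and 1090 for the interaction. Fits to the groups of one comparison, with 2 residual degrees of freedom, gave 2, 11, 7, 16 and 48 genes from 4 to 20 h. Camera with an estimated correlation called 0 lists on the mean over times and 0 at single times, against 7 and 22; the fit to list means called 8 and 9. Leaving 8 h out of the mean gave 215.

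With each plate left out in turn, the mean ranged from 390 to 986 genes, 4 h from 17 to 195, 8 h from 309 to 969, 12 h from 14 to 262, 16 h from 6 to 367 and 20 h from 134 to 470. Any time ranged from 548 to 1292, the interaction from 153 to 548, development from 8905 to 9245 in self and from 8707 to 9156 in chimeric mixes, and the lists from 6 to 9 on the mean and from 20 to 24 at single times. The lowest counts came without chimeric plate 1 of 16 h for the mean (390), any time (548) and 16 h (6), without self plate 1 for 4 h (17) and 12 h (14), without self plate 2 for 8 h (309) and 20 h (134), and without self plate 2 of 20 h for the interaction (153). The highest counts more than 1.5 times larger came without self plate 2 for 4 h (195) and 16 h (367), and without either self plate of 12 h for 20 h (470).

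Over all alternatives 25616 values of named genes were compared. Of these 23925 kept direction and side of the threshold, 1238 no longer passed it, 452 newly passed it, and 1 reversed: act33 on the mean over times stood at 0.03 (adjusted p = 0.893) with 20 h left out of the mean. The signal over background limited the faint genes, which have bounds in place of folds.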

Other observations

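The set of genes seen in 1 kind of mix alone was chosen after its values were seen; the lists were fixed beforehand.

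Of the lists not called on the mean over times, cell adhesion had 4 of 19 genes higher (adjusted over the list alone, 6; camera adjusted p = 0.101) and the tgr family 3 of 26 (adjusted over the list alone, 3; 0.186). Of the counting factor and chalone genes 2 of 10 were lower (adjusted over the list alone, 3; 0.0941), and of the transcription factor genes 4 of 89 were higher and 8 lower (adjusted over the list alone, 5 and 8; 0.252). Polyketide synthase genes had 2 of 16 higher (0.465), ABC transporters 1 of 53 higher and 2 lower (0.252), cytoskeleton and motility 2 of 83 higher and 1 lower (0.694), actins 1 of 7 lower (0.694), oxidative stress 1 of 14 lower (0.289), prespore and spore 1 of 23 lower (0.694), heat shock and chaperones 2 of 26 lower (0.859), and sensor kinases and receptors 2 of 57 lower (0.859). No single gene was called by limma over all genes in the lists of cAMP signalling and aggregation (30 genes, adjusted p = 0.969), DIF-1 pathway (9, 0.252), proteasome (38, 0.773), autophagy (12, 0.694), calcium-binding proteins (17, 0.694) and candidate social genes (6, 0.994). With an estimated correlation the adjusted p of these 18 lists ran from 0.39 to 0.994. The discoidins and the hssl family, with 1 measured gene each, and cytochrome P450 and retrotransposons, with 0, were not tested.

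The 13 genes seen on none of the 20 self arrays and on all 4 chimeric arrays of a time were DDB_G0272706, DDB_G0288419, DDB_G0283429, DDB_G0278667, DDB_G0283301, DDB_G0281035, DDB_G0294080, DDB_G0271188, DDB_G0278469, DDB_G0291736, DDB_G0281755, DDB_G0268952 and DDB_G0281629. The 2 genes of the reverse kind were DDB_G0293648 and DDB_G0277611. In the common reference, 8 of the 13 were seen on 0 arrays. DDB_G0288417 and DDB_G0288419, which rose together, lie next to each other in the reference gene table.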
